A study of Homo sapiens with 2 samples.

How the data were processed

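Expression data from 293T cells, a transformed human embryonic kidney line carrying the SV40 large T antigen, were analysed from 2 Affymetrix oligonucleotide arrays of the U133 Plus series, which cover the human genome. Each array carried biotin-labelled antisense RNA made from RNA recovered by immunoprecipitation. One array came from cells given synthetic miR-941 and precipitated with an antibody to Ago2, the Argonaute protein that holds microRNAs on their target mRNAs. The other came from cells given a scrambled oligonucleotide. Both oligonucleotides were used at 30 nmol/l. The labels of the control array disagree: its title and description call it an Ago2 precipitate, while its antibody entries name nonimmune IgG beads. If the antibody entries hold, the arrays differ in the transfected oligonucleotide and in the antibody together, and these cannot be told apart. The groups were taken from the transfected oligonucleotide. There was 1 array per group.

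The deposited values, 1 per probe set, were quantified by the authors with RMA in R, per the series' design text and the labels. They were taken here as log2 values. The submitters' processing notes name RMA, affy and MAS5 without versions and without saying what each was used for. Neither the scale nor any centring of the values is written in the sources used here. A 16-bit scanner reading has a natural logarithm of at most 11.1, and the deposited values reached 13.6 on the control array and 13.7 on the miR-941 array, which leaves log2 as the scale if the values are logarithms of scanner brightness. Array medians were 0.92 and 0.98. Detection calls were not used here. Of the 54675 probe sets, 11808 (21.6%) held exactly the same value on both arrays. Near the floor the differences took a small number of repeated values, so dim probe sets give a coarser difference than bright ones.

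Probe sets were named from the platform annotation table: 41091 had 1 gene symbol, 1801 had several, 11721 had none there, and 62 were Affymetrix controls. Only those with 1 symbol entered the gene comparison. Symbols were updated through the Entrez identifier to the RefSeq gene table of GRCh38.p14, which held 41037 of the 41091. Annotation coordinates are not printed, since no genome build is named for the array values in the sources used here. The named probe sets stood for 19775 genes. A gene was represented by its brightest probe set over both arrays and was taken as detected when the mean of its 2 values was above 0.92, the median of that mean over all probe sets other than controls. This left 13150 genes.

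The difference is the log2 value of the miR-941 array minus that of the control array. With 1 array per group no test was possible and no p-value is given; the number of arrays limits the precision. Genes were counted at a difference of 1 (2-fold) or more in either direction. As the only measure of technical spread, the detected probe sets of one gene were compared with each other; they are not replicates, and their spread also holds differences between transcript forms. For 23 gene lists, the median difference of the detected members was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and described as standing apart when under the 2.5th or over the 97.5th percentile. These percentiles describe these 2 arrays and say nothing of other cultures. On simulated differences (the real ones shuffled within level bins over 13150 genes), 4% of 200 unchanged lists of 40 genes stood apart, and of 100 lists shifted by each size 23% were found at 0.1 and 97% at 0.2. Of genes given a shift of 1, 63% were counted as 2-fold higher, and of genes given a shift of 2, 100%.

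The lists, the detection rule and the rule for named genes were fixed before the data were examined. The named genes are the 12 with the largest difference in each direction, the 5 in each direction with the largest median difference among genes with 3 or more detected probe sets that all differ one way, the 2 highest and 2 lowest members of each list, and a fixed set of genes of the hedgehog and insulin pathways, the Argonaute, DICER1 and TNRC6 genes, and DNAJC5, whose intron holds the miR-941 genes. The lists cover hedgehog, insulin and Wnt signalling, neurotransmission, the small RNA silencing machinery, targets of the let-7, miR-17 and miR-16 families, ribosomal proteins, translation factors, mitochondrial genome transcripts, the nuclear-encoded respiratory chain, replication-dependent histones, the secretory pathway, long noncoding RNAs, KRAB zinc finger genes, the cell cycle, the interferon response, immediate early mRNAs, the stress response, the proteasome, splicing, ubiquitous reference genes, kidney, neural and filament genes described in the parent line of 293T, and markers of other cell types. Alternatives were the mean over probe sets, leaving out probe sets with the suffixes _x_at and _s_at, no level filter or the 75th percentile, a loess trend removed (span 0.3), quantile normalization, and thresholds of 1.5-fold and 4-fold. A planned comparison of genes with and without a match to the miR-941 seed was not made, since transcript sequences were not used here; the pseudocount alternatives did not apply to values on a log scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.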

Results

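RNA bound in immunoprecipitates of 293T cells was profiled to ask which mRNAs are recovered with Ago2 after miR-941, a microRNA found in humans, is added in excess. Of the 2 arrays, 1 held the Ago2 precipitate of cells given synthetic miR-941 and 1 held the precipitate of cells given a scrambled oligonucleotide. The title of the control sample calls it an Ago2 precipitate and its antibody entry names nonimmune IgG beads, so the oligonucleotide and the antibody cannot be told apart if the entry holds. Neither array has a replicate, so each difference compares these 2 arrays and has no replicate check. Neither holds input or total RNA, so a difference in recovery cannot be told from a difference in mRNA level in the cells. Values are the authors' expression values per probe set, taken as log2, with array medians of 0.98 (miR-941) and 0.92 (control). Over all 54675 probe sets the arrays correlated at Pearson's r = 0.992 and Spearman's rho = 0.939, a correlation across probe sets, which are not independent replicates.

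The arrays differed by 2-fold or more for 68 of 13150 detected genes, 30 higher and 38 lower on the miR-941 array. The largest difference was in DHX38, which encodes a helicase of the spliceosome: its only probe set read 3.76 on the control array and 1.59 on the miR-941 array, a log2 difference of -2.16. DCAF17 followed at -1.72, SPMIP5 at -1.46, ANKRD26 at -1.44, ULK1 (the kinase that starts autophagy) at -1.40, APOBEC3B (a DNA cytidine deaminase) at -1.39 and NAPRT (an enzyme of NAD synthesis) at -1.38. MAGI3, a scaffold of cell junctions, had -1.30, BTBD9 -1.29, the unconventional myosin MYO1E -1.28, the secretory pathway kinase FAM20C -1.26 and RASAL3 -1.25. On the higher side, the 12 largest differences included the long noncoding RNAs ZEB1-AS1 (1.65), MAP3K2-DT (1.51), NIFK-AS1 (1.32) and DLG5-AS1 (1.07). The protein-coding genes were AAAS, which encodes a nuclear pore protein (1.47), CAB39L (1.28), the complex III assembly factor UQCC2 (1.25), WBP2 (1.25), ZSWIM3 (1.20), TEX10 (1.19), ARHGAP42 (1.14) and the small GTPase RHOF (1.06).

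Most of these genes were dim: the median of their mean levels was 2.13, and 41 of the 68 rested on a single probe set. Differences of the 2 brightest detected probe sets of a gene had a within-gene SD of 0.29 (log2), pooled over 6106 genes. They correlated at r = 0.16 (95% bootstrap interval over genes 0.13 to 0.19). The differences of all detected genes had an SD of 0.30. Among the genes above, the second DCAF17 probe set differed in the other direction, as did 1 of 2 for CAB39L, 2 of 4 for RHOF, and 1 of 3 each for BTBD9 and FAM20C, while all 3 MAGI3 probe sets and both ANKRD26 probe sets were lower. Their medians over probe sets were -0.54 for DCAF17, 0.53 for CAB39L, 0.15 for RHOF, -0.23 for BTBD9, 0.00 for FAM20C, -0.26 for MAGI3 and -0.92 for ANKRD26. Without _x_at and _s_at probe sets, CAB39L had -0.23 and ANKRD26 -0.40. Only 11 of the 68 had a mean level above the 75th percentile of all probe sets, 4 higher and 7 lower. Of genes with 2 or more detected probe sets that all differed the same way, 1 was 2-fold higher and 9 were 2-fold lower, a restriction added after seeing the data.

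**Figure D1:**
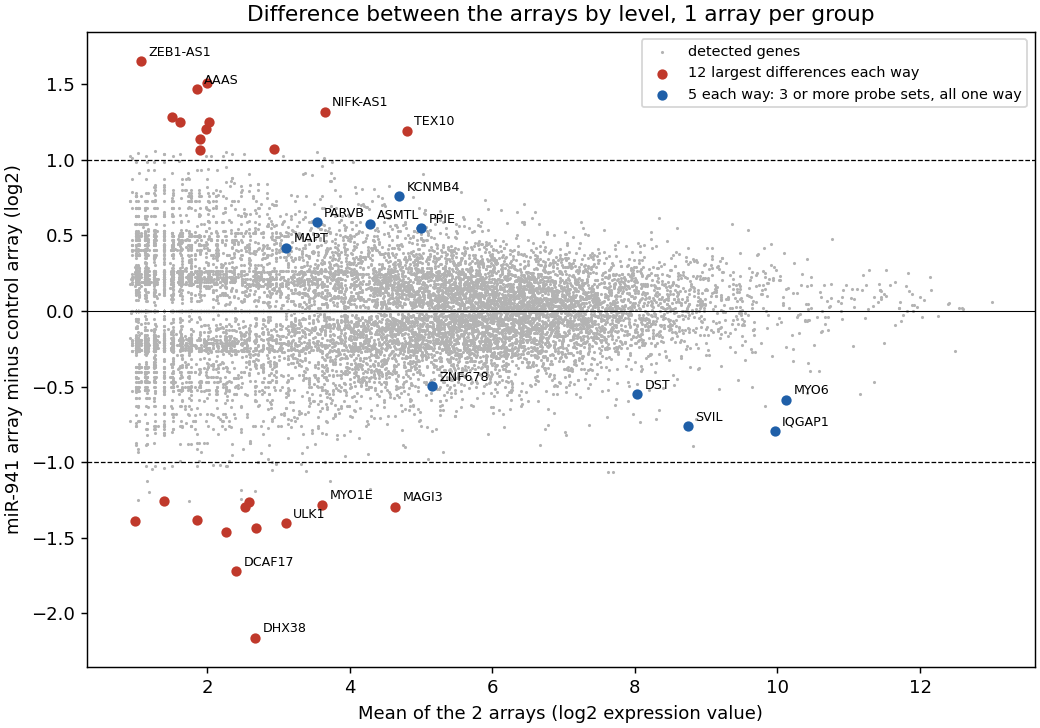
Log2 difference (miR-941 array minus control array) of 13150 detected genes against their mean log2 level, with 1 array per group and dashed lines at 2-fold. Red points are the 12 largest differences in each direction, mostly of dim genes, and blue points the 5 genes in each direction with 3 or more probe sets that all differ one way, plotted at their brightest probe set (IQGAP1 at -0.79).

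Among genes with 3 or more detected probe sets that all differed one way, IQGAP1 had the lowest median on the miR-941 array. IQGAP1, a scaffold that links signalling to actin, had a median log2 difference of -0.79 ± 0.22 (SD over 3 probe sets). SVIL (supervillin, which ties actin and myosin to the membrane) had -0.76 ± 0.33 over 3 probe sets. Its brighter probe sets, both _s_at, had -0.76 and -0.82. Its remaining detected probe set had -0.23, but read only 1.24 on the control array and 1.01 on the miR-941 array, near the detection level of 0.92. DST (a giant linker of cytoskeletal filaments) had -0.74 ± 0.34 over 4, and the myosin MYO6 -0.73 ± 0.23 over 3. All 3 probe sets of IQGAP1 and all 3 of MYO6 are _s_at, so neither gene has a value once _x_at and _s_at probe sets are left out. The remaining gene named on this side was the zinc finger gene ZNF678, at -0.76 ± 0.32 over 3. The 5 named on the higher side were KCNMB4, a subunit of calcium-activated potassium channels (0.76 ± 0.21, 3 probe sets), PARVB, an adhesion protein that also binds actin (0.66 ± 0.29, 4), the microtubule protein tau gene MAPT (0.65 ± 0.41, 4), ASMTL (0.57 ± 0.18, 3) and the cyclophilin PPIE (0.55 ± 0.28, 3). Of 2578 genes with 3 or more detected probe sets, 493 had all of them differing one way, 276 lower and 217 higher, where shuffling the differences among probe sets of like level gave 332 on average (range 278 to 380 over 100 shuffles). Of 4874 genes whose 2 brightest detected probe sets both differed between the arrays, 57.8% had them in the same direction, against 48.5% to 51.8% over the same shuffles (60.3% against 46.7% to 52.2% above the 75th percentile of level). Probe sets of the same gene share 1 hybridisation per array, so these SDs do not include variation between cultures or precipitates.

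Genes of the respiratory chain, the proteasome and the secretory pathway were slightly higher on the miR-941 array. Of 63 detected nuclear-encoded respiratory chain genes, 55 were higher and 8 lower, with a median log2 difference of 0.19 and none past 2-fold. ATP5F1A and NDUFB1, subunits of ATP synthase and complex I, each had 0.48, while the complex I genes NDUFS4 and NDUFV2 had -0.27 and -0.23. Of 27 proteasome genes 23 were higher and 4 lower (median 0.16), from PSMC4 (0.44) and PSMB1 (0.37) to PSMC2 (-0.33) and PSMC3 (-0.37). Over 3 probe sets each, the median was 0.19 for PSMB1 and -0.69 for PSMC2, with all 3 of PSMC2 lower. Of 45 secretory pathway and ER chaperone genes 33 were higher and 9 lower (median 0.11), with SDF2L1 at 0.53, KDELR1 at 0.31, DNAJB11 at -0.24 and RPN1 at -0.26. The medians lay at the 100th, 99.7th and 99.1th percentile of level-matched random lists, whose central 95% ran from -0.03 to 0.09, from -0.07 to 0.11 and from -0.05 to 0.09. These were the 3 of 23 lists that stood apart, where random lists of genes of like level would give 1.15. Members of one list may vary together, so that number is not a rate for lists of related genes. On the same arrays the 5' control of the actin mRNA had -0.66 and its 3' control -0.04, the 5' and 3' controls of GAPDH had -0.19 and 0.05, and those of 18S ribosomal RNA ran from -0.45 to -0.08. The secretory list reached only the 96.9th percentile when differences were averaged over probe sets.

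**Figure D2:**
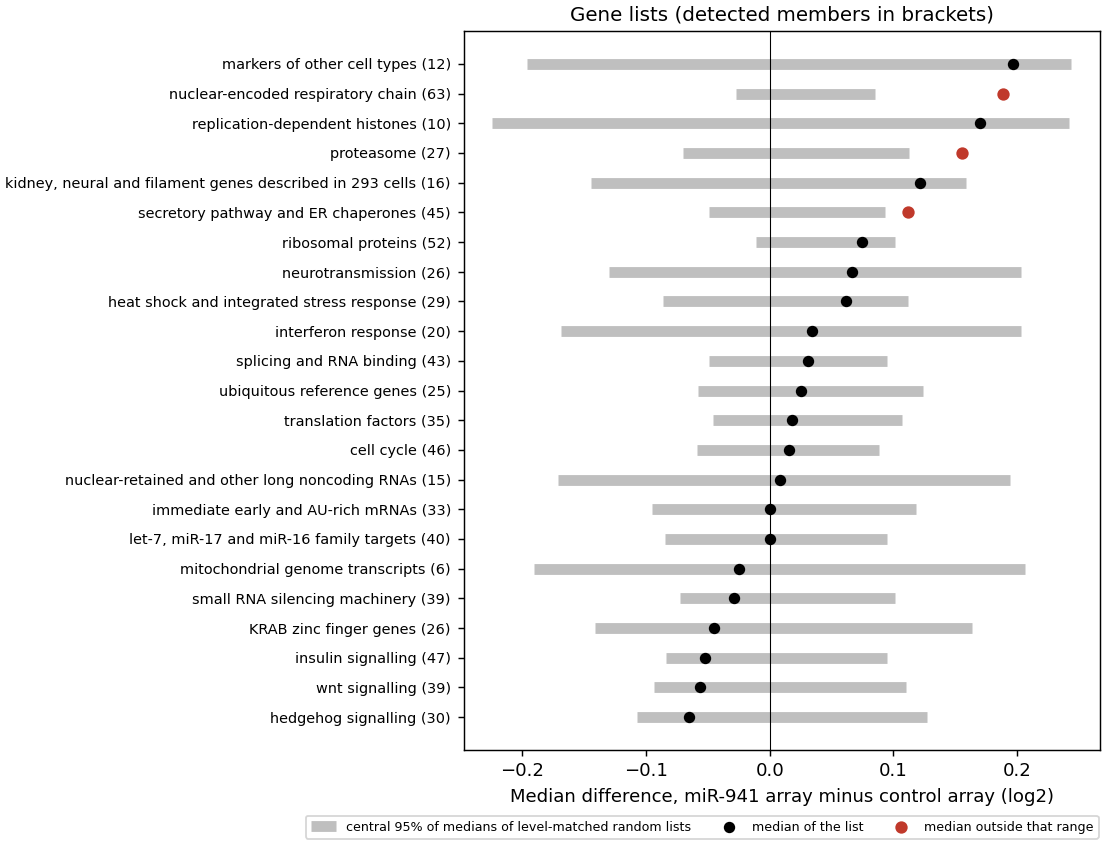
Median log2 difference (miR-941 array minus control array) of each of 23 gene lists, as points, over the central 95% of the medians of 10000 level-matched random lists, as grey bars. The respiratory chain (0.19), proteasome (0.16) and secretory pathway (0.11) lists lie to the right of their bars, and the other 20 lie within them.

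Hedgehog and insulin signalling, pathways that were linked to miR-941, did not stand apart as lists from other genes of their level. A list median can miss a change in a few members, and genes with a miR-941 seed match were not compared. These medians therefore cannot decide for or against that link. No detected hedgehog gene differed by 2-fold: 12 of 30 were higher, 16 lower and 2 equal, with a median of -0.07 (7.57th percentile). HHIP, which binds hedgehog ligands, had 0.88, but its 2 detected probe sets differed in opposite directions (median 0.18), and the kinesin KIF7 had 0.39. The ciliary gene IFT88 had -0.86 on 1 probe set and the hedgehog co-receptor GAS1 -0.55, lower on both detected probe sets. The receptor component SMO had 0.26, the pathway inhibitor SUFU -0.46 (with its other detected probe set higher and a median of -0.13), and the transcription factor GLI1 read 1.10 on both arrays. That GLI1 reading is near the detection level of 0.92, so it does not show an unchanged mRNA. SMO (1.95 control, 2.21 miR-941) and SUFU (2.13 and 1.68) were dim as well. Among 47 insulin signalling genes, 18 were higher and 26 lower (median -0.05, 8.36th percentile). RPTOR, the scaffold of mTOR complex 1, had -1.19 on its 1 probe set, the only member past 2-fold, and the receptor substrate IRS2 had -0.79 with both probe sets lower. IRS1 had -0.37 and FOXO1 -0.17, with the 2 detected IRS1 probe sets differing in opposite directions (median 0.03). The brighter IRS1 probe set read only 1.57 on the control array and 1.20 on the miR-941 array. PYGB (glycogen phosphorylase) had 0.53 and MAPK3 0.44. PPARGC1A was below the detection level. Wnt signalling gave a median of -0.06 over 39 genes (7.31th percentile), with APC at -0.53 and lower on all 3 detected probe sets, DVL3 at -0.34 (median -0.17 over 2 probe sets), DKK1 at 0.73 and LRP5 at 0.40. The median for neurotransmission was 0.07 over 26 detected genes (76.8th percentile), with GRIK5 at 0.65, MAOA at 0.59, SLC17A7 at -0.52 with 1 of its 2 probe sets higher (median -0.17), and GABBR2 at -0.52 with all 3 lower (median -0.34). The only detected GRIK5 probe set, an _x_at one, read 1.06 on the control array and 1.71 on the miR-941 array.

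The small RNA silencing machinery did not stand apart as a list: of 39 genes 16 were higher on the miR-941 array and 21 lower, with a median of -0.03 (14.2th percentile). AGO2 read 8.02 on the control array and 7.44 on the miR-941 array, a difference of -0.58 on its 1 probe set, and AGO4 had -0.60. TNRC6B, which encodes a partner of the Argonaute proteins in repression, had a median of -0.44 ± 0.23 (SD over 7 probe sets), with 6 lower and 1 equal. DICER1, the nuclease that makes microRNAs from their precursors, had a median of -0.42 ± 0.25 over 4 probe sets, all lower. TNRC6C had -0.76 and TNRC6A -0.45 on the brightest probe set, with medians over probe sets of -0.24 and -0.08. AGO3 had 0.39 and AGO1 0.03, with 2 of 4 AGO1 probe sets lower and a median of -0.14. The helicase MOV10 had 0.63 and the exonuclease XRN1 0.51, with medians over 2 probe sets of 0.40 and 0.16, and 1 of the 2 of XRN1 was lower. Known targets of the let-7, miR-17 and miR-16 families had a median of 0.00 over 40 genes, 18 higher and 17 lower, at the 44.2th percentile of lists whose central 95% ran from -0.08 to 0.09. Within that list IGF2BP1 had 0.52, CDC25A 0.41, BMPR2 -0.58 and BCL2 -1.05, but 2 of the 3 detected BCL2 probe sets and 1 of the 4 of BMPR2 were higher, and 2 of the 3 of CDC25A lower. Their medians were 0.18 for BCL2, -0.13 for BMPR2 and -0.17 for CDC25A. DNAJC5, the host gene of miR-941, had -0.26 on its brightest probe set and a median of 0.09 ± 0.26 over 3.

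**Figure D3:**
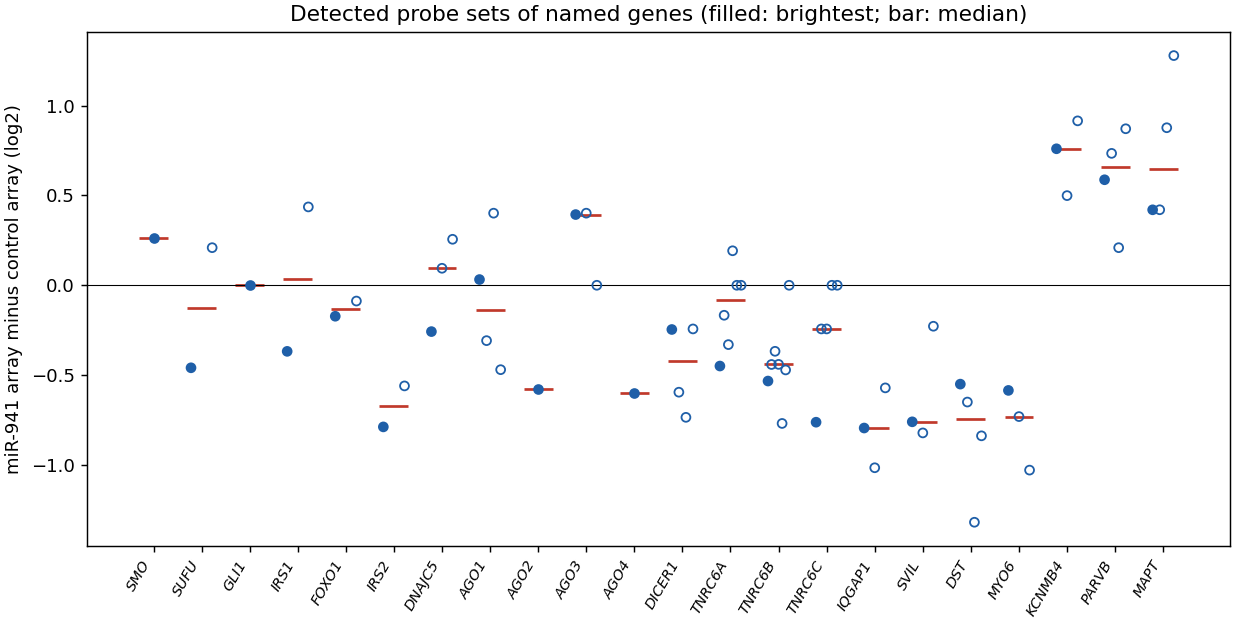
Log2 difference (miR-941 array minus control array) of each detected probe set of named genes, with the brightest probe set filled and a red bar at the gene's median. The probe sets of IQGAP1, SVIL, DST, MYO6 and DICER1 all lie below 0, while those of SUFU, IRS1 and AGO1 lie on both sides.

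Genes of translation, the cell cycle and stress lay within the range of level-matched lists. Ribosomal proteins were higher for 45 of 52 members, and their median of 0.07 was at the 84.6th percentile of level-matched lists; with the loess trend removed, 31 of 52 were higher and the median was 0.0346. RPLP2 had 0.53 and RPL8 -0.15. Over 3 probe sets each, the translation factor genes EIF2S1 and EIF5A had medians of 0.27 and -0.15, with 1 of the 3 of EIF5A equal on both arrays. Medians were 0.02 for translation factors (EIF2S1 0.43, EIF5A -0.59), 0.02 for the cell cycle (MCM2 0.43, CENPF -0.46), 0.03 for splicing (SF3A1 0.30, SRSF10 -0.40), 0.03 for ubiquitous reference genes (TFRC 0.58, ACTB -0.24) and -0.03 for 6 mitochondrial genome transcripts (ND2 0.18, ND4 -0.12). The stress list had a median of 0.06 (ASNS 0.45, SLC3A2 -0.39), the interferon list 0.03 (IRF1 0.68, IRF9 -0.59) and the immediate early list 0.00, where FOSB had 1.04 and CCN1 -0.68, with a median of -0.03 over 2 CCN1 probe sets that differed in opposite directions. Detected probe sets of ND4 (median -0.0369), ZNF585A and SRSF10 also lay on both sides of 0. The medians were -0.04 for KRAB zinc finger genes (ZNF585A 0.68, ZNF93 -0.76), 0.01 for 15 long noncoding RNAs (GAS5 0.75, JPX -0.996) and 0.17 for 10 detected histone genes (H1-2 0.78, H2AC17 -0.47). Kidney, neural and filament genes described in the parent line of 293T had a median of 0.12 over 16 members (STMN1 0.44, INA -0.59). Of 38 markers of other cell types on the array, 12 passed the detection level, with a median of 0.20 at the 90.2th percentile, VWF at 0.73 (median 0.36 over 2 probe sets) and KRT5 at -0.37. VWF (0.66 control, 1.39 miR-941) and KRT5 (1.45 and 1.08) read near the detection level. HBB, which encodes beta globin, read 6.95 and 7.54, with 3 of its 4 probe sets higher and 1 lower. The 3 higher ones are all _x_at. The other read 1.49 on the control array and 0.76 on the miR-941 array, near the detection level, so expression of HBB itself is not shown. Without _x_at and _s_at probe sets the splicing list (0.16) and the genes described in the parent line (0.34) stood apart, and the medians were -0.10 for the markers of other cell types and 0.02 for KRAB genes. With differences averaged over probe sets, Wnt signalling (-0.0931) and long noncoding RNAs (-0.17) stood apart. The noncoding RNA list also stood apart on the lower side without _x_at and _s_at probe sets (-0.24) and above the 75th percentile of level (-0.31), and on the higher side with no level filter (0.19), where histones (0.19) stood apart too.

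The control probe sets for the actin mRNA differed more at its 5' end than at its 3' end. The ACTB 5' control read 7.15 on the control array and 6.49 on the miR-941 array (-0.66), the middle control -0.37 and the 3' control -0.04. For GAPDH the same 3 positions had -0.19, -0.07 and 0.05. The 3' value exceeded the 5' value by 2.71 (control) and 3.32 (miR-941) for ACTB and by 1.18 and 1.42 for GAPDH. The 18 bacterial hybridisation controls, added in equal amounts to check the hybridisation, had a median difference of 0.10 (range -0.10 to 0.17), and the 3 probe sets of 18S ribosomal RNA had -0.45, -0.44 and -0.08.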

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

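No test here was fixed before the result was seen. Probe sets with no gene symbol or several took no part in the gene comparison, and they were looked at for differences of the same size. Of 3935 such probe sets above the detection level, 16 were at least 2-fold higher on the miR-941 array than on the control array (0.407%) and 19 at least 2-fold lower (0.483%). Of the 23317 detected probe sets with 1 symbol, 84 were at least 2-fold higher (0.360%) and 113 lower (0.485%). No explanation was tested.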

How the results depend on the processing

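The alternatives were fixed before the data were examined, except 3 chosen after seeing them: random lists matched also on gene span, values below the detection level set to it, and the restriction to 2 or more probe sets that all differ one way. No paired analysis was possible because each group has 1 array and its replicate number is only a name, and no array could be left out. The seed match and pseudocount alternatives were not run. Counts of 2-fold genes (30 higher, 38 lower) were 4 and 7 above the 75th percentile of level, 24 and 18 with differences averaged over probe sets, 22 and 30 with low values set to the detection level, and 1 and 9 with probe sets that all differ one way. At 1.5-fold they were 387 and 378, and at 4-fold 0 and 1 (DHX38). A stricter filter tests fewer genes. The correlation between the 2 brightest detected probe sets of one gene was 0.29 above the 75th percentile, against 0.16. CAB39L had -0.23 in place of 1.28 without _x_at and _s_at probe sets, which took out its brightest one. The respiratory chain and proteasome lists stood apart under each alternative, and the secretory list under all but the mean over probe sets (0.0829, 96.9th percentile). Without _x_at and _s_at probe sets, medians were 0.13 for the respiratory chain, 0.11 for ribosomal proteins, -0.24 for noncoding RNAs, 0.0238 for KRAB genes, 0.15 for immediate early genes, 0.16 for splicing, 0.0749 for reference genes, 0.34 for genes described in the parent line and -0.10 for other cell types. Averaging over probe sets gave -0.0931 for Wnt and -0.17 for noncoding RNAs. With no level filter, histones had 0.19, noncoding RNAs 0.19, interferon genes 0.18 and other cell types 0.0535. Above the 75th percentile, Wnt had -0.10, noncoding RNAs -0.31 and genes described in the parent line 0.00. Ribosomal proteins had 0.0346 with the loess trend removed and 0.0424 after quantile normalization. For the lists the cause was not tested. The remaining 149 values of counts, lists and agreement under an alternative stayed within the limits used; for named genes 239 did and 15 more did not. Brightness over background limits the dim genes.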

Other observations

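The symbol families, the lists of actin-binding and other large proteins, the matching on gene span, and the tests on large proteins not displayed before, on an equal shift of actin cytoskeleton mRNAs, on _x_at and _s_at probe sets and on microRNA targets were chosen after the result was seen. The lists were written after the differences of many of their members had been looked at, large proteins were first compared over all members, and the bound first written for small actin-binding proteins (a median above the mean of level-matched lists) was not met.

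Genes grouped by the letters that start their symbols (121 groups of 12 or more detected genes) showed further differences. Of 14 detected MYO genes, which encode unconventional myosins, 11 were lower on the miR-941 array and 2 higher, with a median log2 difference of -0.59, while the central 95% of level-matched lists ran from -0.14 to 0.17. MYO5B had -1.06, MYO5C -0.74, MYO1D -0.69, MYO9A -0.65 and MYO5A -0.59. These genes were picked after their values were seen. The counts use the brightest probe set, and some members were mixed. MYO19 had -0.19 but a median of 0.41 over 3 probe sets, 2 of them higher. MYO9B had -0.73 but a median of 0 over 3, with 1 lower and 1 higher. Of 369 ZNF zinc finger genes 194 were lower and 140 higher (median -0.07), of 38 ZBTB genes 25 were lower and 9 higher (median -0.17), and of 14 DENND genes, which encode activators of Rab GTPases, 11 were lower and 1 higher (median -0.21).

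On the higher side, all 12 detected NDUFA genes of complex I and all 12 PSMD genes of the proteasome cap were above 0 (medians 0.24 and 0.16); both groups share genes with the fixed lists. Of the mitochondrial ribosomal protein genes, 39 of 49 MRPL and 21 of 27 MRPS genes were higher (medians 0.12 and 0.12). TRAPPC genes, which encode a vesicle tethering complex, were higher for 12 of 15 (median 0.26), NUDT hydrolases for 15 of 19 (0.20) and annexins for 9 of 12 (0.23). In all, 21 of the 121 groups stood outside the central 95% of level-matched lists, where random lists of genes of like level would give 6.05. Each group named here kept its sign with the loess trend removed and after quantile normalization. These steps moved the medians little (MYO -0.61 and -0.60, against -0.59), and the groups were picked from the same values. The kept signs therefore add no support. The groups were matched on level only. Gene span and RNA integrity (the ACTB 5' control had -0.66 and the 3' control -0.04) therefore stay open for the lower and the higher groups alike.

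Of 48 detected genes of large actin-binding and myosin proteins, 42 were lower on the miR-941 array and 3 higher, with a median of -0.50 (95% bootstrap interval over genes, -0.62 to -0.31). That value is raised in size by choice, since 33 of the 56 genes listed had been looked at before the list was written. Over the 15 detected members not looked at, the median was -0.21 (-0.31 to -0.04) against -0.14 (-0.22 to -0.07) for 56 other large proteins, which leaves lower values of large mRNAs in general undecided, since the lowest members were among those looked at and left out. The list kept -0.49 over the 38 genes left without _x_at and _s_at probe sets. Small actin-binding proteins had a median of 0.00 over 34 genes (SD 0.21), above the upper end of the large list's interval by 0.31. The large list was partly picked from these same values. Neither value can therefore argue against an effect of those probe sets, or, as a gap from that list, against an equal shift of all actin cytoskeleton mRNAs. Over the members not looked at, the interval reached up to -0.04, and the small list's median lay above that by less than its SD. The 28 small genes not looked at had a median of 0.00 (95% bootstrap interval over genes, -0.06 to 0.10). An equal shift near -0.21 lies outside that interval, which argues against a shift of that size in those small genes. Smaller equal shifts stay undecided, since that interval overlaps the one of the large members not looked at (whole small list at the 32.2th percentile). RNA integrity (the 5' actin control had -0.66), mRNA levels in the cells, the antibody, miR-941 and chance between single precipitates also stay open.

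The higher values of the respiratory chain, proteasome and secretory pathway lists might follow gene size, since the difference correlated with gene span at Spearman's rho = -0.10 across 13138 detected genes, which are not independent replicates. Against lists matched on level and gene span, their medians stayed at the 100th, 99.9th and 99.2th percentile, which argues against gene span as the whole cause. Gene span is not mRNA length, so a bias on mRNA length stays open. RNA integrity and 3' bias stay open too, since the 5' actin control had -0.66 and the 3' control -0.04, as do mRNA levels in the cells, the antibody and miR-941.

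The arrays correlated at r = 0.992 and Spearman's rho = 0.939 across probe sets, while an antibody entry describes the precipitates as different. Such a correlation largely reflects levels that differ from probe set to probe set, so it does not bear on the antibody. If both held the same kind of precipitate, known targets of microRNAs present in the cells would not be richer on the miR-941 array. The let-7, miR-17 and miR-16 target list lay at the 44.2th percentile of level-matched lists, a value seen before this comparison was written. The levels of these microRNAs were not measured here. One kind of precipitate would give that percentile, but so could low levels of these microRNAs or RNA carried over without antibody binding. Of simulated lists, 97% were found when shifted by 0.2 but 23% when shifted by 0.1. The antibody of the control array stays unknown.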
